A study of Mus musculus with 2 samples.

How the data were processed

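The series holds ChIP-seq of Ehf in mouse corneal epithelium with an input control, 1 library of each from tissue pooled over 15 mice. Samples were grouped by their titles. The deposited list of Ehf peaks was the only processed file analysed here. It has no header and gives a chromosome, a start, an end, a name and a score for each peak. The submitters' processing notes name Bowtie 0.12.7, bedtools 2.11.2 and the build mm9. All 15384 peak names in the deposited list begin with MACS_peak, which names the peak caller, but its version, its settings and the way the input was used are not given in the sources used here. Peaks were called on a single library, so no agreement between replicates entered the list.

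The score is the authors' own value for each peak, as deposited. Its meaning is not stated in the file or the labels. Early versions of MACS write a scaled log p-value in this column. If that holds here, the lowest score of 50.01 reflects a p-value threshold, the 4 peaks at 3100 may share a ceiling and have no known order, and a difference in score is one in log p, which depends on read depth as well as on enrichment. It was used only to rank, filter and describe peaks within this list. Positions are printed as in the file. The lowest start is 1, and neighbouring peaks neither overlap nor lie closer than 1 bp, so the values do not show whether starts count from 0 or from 1 and a start may be off by 1 bp. The build was checked against chromosome lengths stored in the R package GenomeInfoDb 1.38.1. No peak ended beyond its chromosome in mm9, and 91 did in the next build, mm10.

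The read depth of both libraries is unknown, because the list holds no counts, so no limit of detection could be given. A table of gene names of another build was not used. Planned tests of promoters, of 10 gene lists and of the ETS motif need an annotation or a sequence of mm9 and were not run, and genes near peaks are not analysed here.

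Density was computed as peaks per Mb of full mm9 chromosome length, unsequenced gaps included, with 95% intervals from 1000 bootstrap draws of 1 Mb bins within a chromosome. Spacing was measured edge to edge. The share of peaks with another within 10 kb was compared with 1000 random placements of the same widths on the same chromosome, uniform between its first and last peak, by a one-sided permutation test. Scores of peaks with and without such a neighbour were compared by the difference of medians, with 100000 permutations within chromosomes, two-sided. Windows of 100 kb were chosen greedily by peak count without overlap, with ties taken in chromosome order. Shares of narrow peaks carry 95% Wilson intervals. The named regions follow a rule fixed before the data were examined, which was the 10 highest-scoring peaks, the 5 widest, the 10 densest windows, the densest and the sparsest chromosome and the 5 longest gaps. The mitochondrial chromosome was left out of the ranking of chromosomes by density.

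Alternatives fixed before the data were examined were a score at or above the median, merging of touching peaks, neighbour distances of 5 and 50 kb, placement within 1 Mb bins, leaving out X, Y and M, midpoint distances, mean log2 scores, comparison within 10 width classes and chromosome lengths taken as the span between peaks. The span between peaks as the length of Y, merging of peaks up to 1 kb apart, leaving out the 10 densest windows with the mitochondrial chromosome, and leaving out peaks under 200 bp were added after seeing the data, as was the width of 200 bp itself. The tests were checked on simulated lists of 15384 peaks, 20 for each case. The spacing test gave p of at most 0.05 in 0 of 20 lists placed at random, and in 20 of 20 in which 200 peaks were moved beside another. The score test did so in 1 of 20 lists without a shift and in 20 of 20 with a shift of 10 score units, which is larger than the difference found in the real list. These checks used fewer placements and permutations than the analysis. The random lists were made by the same placement as the test, so they check the computation and not the effect of unsequenced stretches. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, numba 0.67.0, scipy 1.17.1 and matplotlib 3.10.9 was used.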

Results

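Ehf is an epithelial transcription factor of the ETS family, and the study mapped where it binds along the genome in the mouse corneal epithelium, the outermost cell layer of the eye. Epithelium from 15 wild-type mice aged 2 to 3 months was pooled, and 24 ug of its sonicated chromatin was precipitated with an antibody to Ehf. The ChIP library and a library of the input chromatin, which was not precipitated, were sequenced together with single-end reads of 50 bp. The mice are called CB6 in one label and C57Bl/6 in another. There was 1 library per group, so no difference between biological samples could be tested. Every error below refers to a single peak list and gives the spread over genome bins, the spread over random placements or the counting error of a share. The number of reads behind each peak is unknown, since the list gives a position and a score per peak and no counts. No value of the input library was analysed here. Positions are mm9, and no annotation of that build was used, so regions are named by coordinate and not by gene.

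The list held 15384 peaks, which together covered 5.77 Mb, or 0.217% of chromosomes 1 to 19, X, Y and M. Peaks had a median width of 368 bp, with quartiles of 231 and 450 bp. The authors' score had a median of 86.2, with quartiles of 66.9 and 125. It ran from 50.01 to 3100, and 4 peaks shared the highest value, which may be a ceiling of the scale, whose meaning is not stated. Peak width had 2 modes. Of all peaks, 3383 (22.0%) were under 200 bp wide, down to 146 bp, and 4642 (30.2%) were between 350 and 450 bp. The peaks under 200 bp had a median score of 140.02, against 69.5 for those of 350 to 450 bp and 78.7 for all 12001 peaks of 200 bp or more. The 49 peaks over 1200 bp had a median score of 295.

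**Figure D1:**
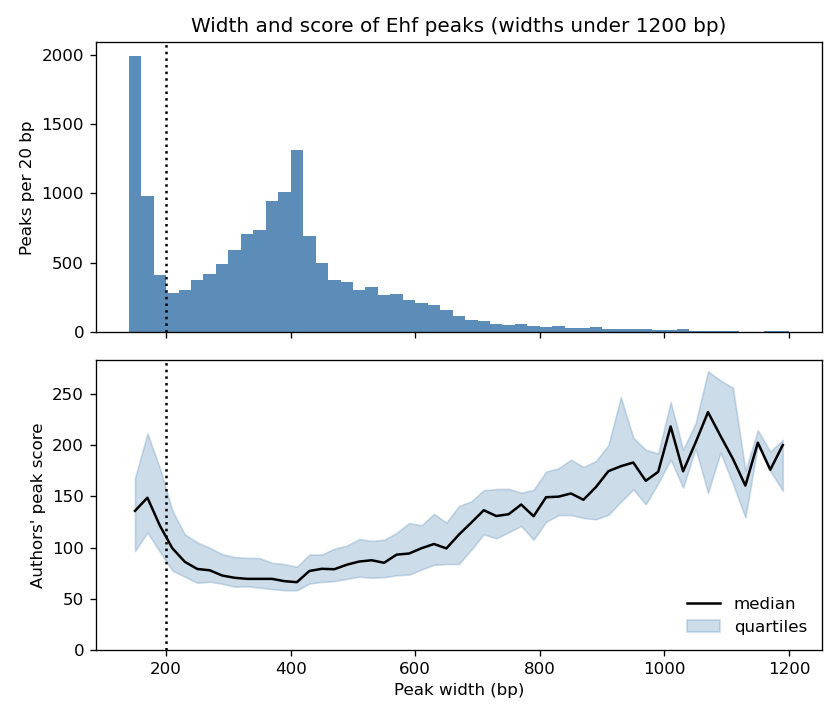
The upper panel plots the number of peaks per 20 bp of width and the lower panel the median (line) and quartiles (band) of the authors' score, for peaks under 1200 bp in the single ChIP library. The dotted line marks 200 bp. The 3383 peaks to its left have a median score of 140.02, above that of the peaks of 350 to 450 bp.

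Chromosome 11, among the most gene-dense mouse chromosomes, carried the highest density of Ehf peaks in the nuclear genome, and the sex chromosomes the lowest. Chromosome 11 held 1084 peaks, or 8.90 per Mb (95% bootstrap interval over 1 Mb bins 7.57 to 10.3). Chromosome 19 followed with 8.04 per Mb (6.50 to 9.86). The pooled density of the 19 autosomes was 6.10 per Mb (5.86 to 6.35). Chromosomes 5, 11 and 19 had intervals above that value, and chromosomes 1, 3, 6, 14 and 16 had intervals below it. The lowest autosome was chromosome 14, with 568 peaks or 4.54 per Mb (3.88 to 5.26). Relative to the other autosomes together, the density of chromosome 11 was 1.49 times as high (1.26 to 1.76).

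The X chromosome held 289 peaks, or 1.73 per Mb (1.41 to 2.11), which was below each of the 19 autosomes. Its density was 0.284 of the autosomal density (0.225 to 0.344). The Y chromosome held 6 peaks, or 0.377 per Mb of its full mm9 length of 15.9 Mb, unsequenced gaps included (0 to 1 per Mb). All 6 lay before 2.77 Mb, and over the span between its first and last peak Y had 2.40 per Mb against 1.80 for X, so which of these chromosomes was the sparsest depended on the length used. The labels do not give the sex of the pooled mice, so the number of copies of X and Y in the chromatin is not known. The peaks called on X had a median score of 88.2. Of them, 34.6% were under 200 bp wide (95% Wilson interval 29.4 to 40.3%), against 21.8% (21.1 to 22.4%) of the autosomal peaks. Among single autosomes this share ran from 17.5% on chromosome 4 (15.3 to 19.96%) to 27.2% on chromosome 13 (23.9 to 30.7%), and the intervals of chromosomes 13 and 18 (26.2%, 22.6 to 30.2%) overlapped that of X. These Wilson intervals cover counting error only.

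**Figure D2:**
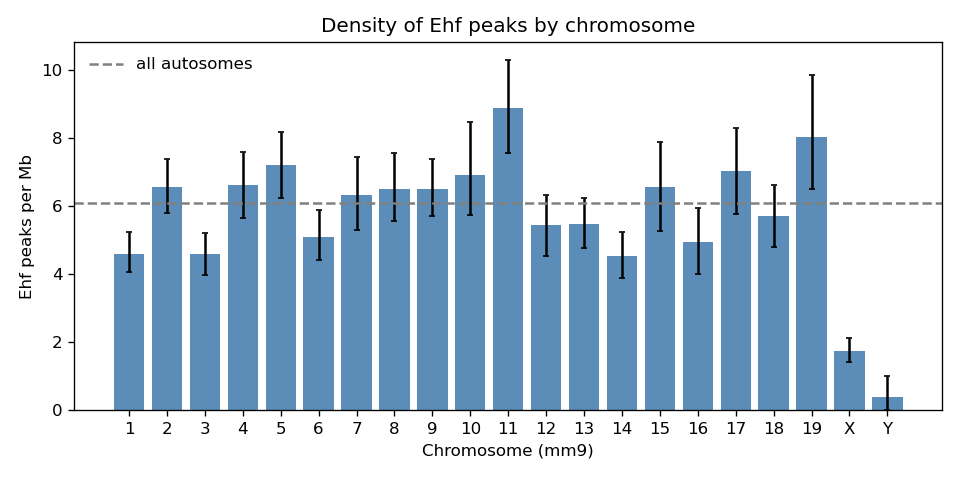
Bars give Ehf peaks per Mb of full mm9 length, gaps included, for each nuclear chromosome, and error bars the 95% bootstrap interval over 1 Mb bins. The dashed line is the pooled density of all autosomes, 6.10 per Mb. Chromosome 11 stands highest at 8.90 per Mb, and X (1.73) and Y (0.377) lie below all autosomes.

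Ehf peaks lay in groups along the chromosomes. Of the 15384 peaks, 27.2% had another peak within 10 kb, against 12.4% ± 0.359 (SD over 1000 placements) when the same peaks were placed at random on their own chromosomes. This was a 2.19-fold excess (one-sided permutation test, p = 0.001, the smallest value 1000 placements can give). When each peak was moved only within its own 1 Mb bin, the random share rose to 18.8% and the excess was 1.44-fold (permutation p = 0.001). For neighbours within 50 kb it was 1.35-fold, 63.5% against 47.0% at random (permutation p = 0.001). The excess was found on each of the 20 chromosomes tested, 1 to 19 and X, where the observed share lay above the highest of the 1000 random placements. Chromosome 11 had 33.6% of its peaks within 10 kb of another, against 17.4% at random, and chromosome 17 had the smallest excess, 24.6% against 14.1%. Chromosome X had 15.2% against 3.60%. Random positions could fall in unsequenced or repeated stretches where no peak can be called, which lowers the random share.

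Chained at 10 kb, the peaks formed 11201 single peaks and 1866 clusters. Of the clusters, 1541 had 2 peaks, 325 had 3 or more, and 24 had 5 or more. The median gap between neighbouring peaks was 66.7 kb. In 806 of 15362 neighbouring pairs (5.25%) the gap was 1000 bp or less. With such pairs joined into 1 region, 19.4% of regions had a neighbour within 10 kb against 11.8% at random (permutation p = 0.001), an excess of 1.64-fold. The random regions were placed over the whole chromosome, and placement within 1 Mb bins was not run on joined regions.

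**Figure D3:**
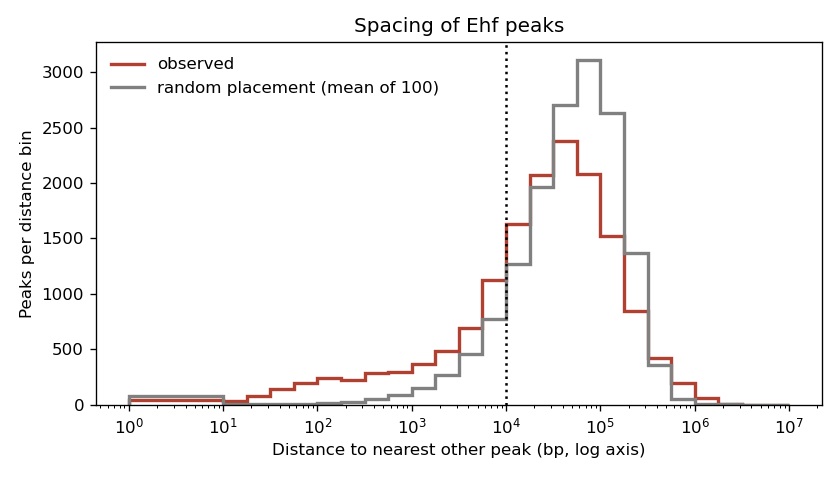
The red line counts peaks by the distance to their nearest other peak (log axis, in bp), and the grey line is the mean of 100 random placements of the same peaks, whose overlapping peaks fall in the first bin. The dotted line marks 10 kb. Observed peaks exceed random ones below 10 kb, apart from the first bin, and 27.2% of them lie there against 12.4%. The excess continues up to 31623 bp and returns beyond 316228 bp.

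The densest window of 100 kb lay at the start of the assembled sequence of chromosome 9, from 2999923 to 3038525. It held 25 peaks in 38.6 kb, which covered 52.6% of that stretch, with a median score of 216. Of these peaks, 10 were at or above the 99th percentile of all scores (332). The next 9 windows held 9 to 14 peaks each, while the highest count in any window of a random placement had a median of 7 and reached 9. With placement inside the same 1 Mb bin the highest count in any window of the genome had a median of 12 and reached 19. The counts of the next 9 windows did not exceed 19, while that of the first window on chromosome 9 did. No window was compared with its own bin alone. With peaks 1 kb or less apart joined, no window held more than 11 regions, so the 25 peaks were not 25 separate regions. Random placement of the joined regions over whole chromosomes reached 10, and placement within bins was not run on them. None of the next 9 windows had a peak at or above the 99th percentile of score.

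Chromosome 10 held 3 of the 10 densest windows. The last of the 10, with 9 peaks, was tied with windows on other chromosomes and on chromosome 10, and was taken by chromosome order. The densest of them ran from 79750922 to 79850634 with 14 peaks, and the others from 79600845 to 79683870 and from 80702645 to 80800839 with 10 peaks each. The whole stretch between the first and the last of them, singled out after its values were seen, held 67 peaks in 1.20 Mb. That is 55.8 per Mb, 8.07 times the density of chromosome 10 as a whole. Their median score was 74.8, below that of the whole list, and 6 of them were under 200 bp wide.

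Other dense windows were found on 5 chromosomes. On chromosome 7, 11 peaks lay from 26022422 to 26107657, with a median score of 75.7. On chromosome 15, 11 peaks lay from 85407976 to 85502600, with a median score of 74.3. Chromosome 2 had 10 peaks from 74493400 to 74565736, with a median score of 81.1, and 9 peaks from 179757766 to 179854348, with a median score of 56.6. On chromosome 11, 10 peaks lay from 117744301 to 117830795, with a median score of 71.7. Chromosome X, despite its low density, had 10 peaks from 11657232 to 11737537, with a median score of 71.7 and a highest score of 216.

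The longest stretch between neighbouring peaks was on X, 13.1 Mb from 20498037 to 33604302. The next was 8.95 Mb on chromosome 7, from 38870322 to 47818516. Chromosome 14 had 5.89 Mb without a peak from 89867979 to 95753585, X a further 5.51 Mb from 39755660 to 45265015, and chromosome 1 a stretch of 5.28 Mb from 113651030 to 118932772. Absence from the list means that no region there passed the authors' threshold at this unknown depth, not that Ehf is absent. Unsequenced or repeated stretches, where no peak can be called, were not set apart and may make up part of these gaps.

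The 10 highest-scoring peaks lay in 5 places. The list holds no copy numbers, so these scores cannot be read as the strongest binding of Ehf. The score of 3100 was reached by 2 peaks on chromosome 2 (98502276 to 98503248 and 98506291 to 98507603) and by 2 adjoining peaks on chromosome 17 (39979889 to 39984199 and 39984345 to 39985879). Chromosome 9 had 4 of the 10 highest peaks in its first dense window, with scores from 1415 to 1813. The other 2 stood alone. A peak of 758 bp on chromosome 9 from 35112688 to 35113446 scored 2084 and was 102 kb from its nearest neighbour. A peak of 651 bp on chromosome 11 from 108872868 to 108873519 scored 2057 and was 83.7 kb from its nearest neighbour.

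The widest peak, 6834 bp on chromosome 11 from 3032443 to 3039277, scored 133. The next 2 in width lay on the mitochondrial chromosome, from 1 to 5577 and from 10904 to 15951, with scores of 739 and 997. Together these 2 peaks covered 65.2% of the 16.3 kb of mitochondrial DNA. The fourth and the fifth in width were the wider peak on chromosome 17 named above (4310 bp) and one of the peaks in the chromosome 9 window (3024364 to 3027914, 3550 bp).

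Grouped peaks did not score higher than single ones. The 4183 peaks with another within 10 kb had a median score of 82.8 and the 11201 others 87.7, a difference of -4.88 (two-sided permutation test within chromosomes, p = 1e-05, the smallest value the 100000 resamples can give). Peaks are not replicates, so this p describes the list only. The difference was not found within width deciles. There the size-weighted mean of the differences of medians was 0.617 (permutation within deciles, p = 0.47). Among peaks of 200 bp or more, with only such peaks counted as neighbours, the difference of medians was -0.32 (permutation p = 0.7).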

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

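The excess of grouped peaks over random placement kept its direction and its permutation p of 0.001 in all 10 alternatives, each applied singly. Its size changed, from 2.19-fold to 1.35-fold for neighbours within 50 kb (63.5% against 47.0% at random) and 1.44-fold for placement within 1 Mb bins. It was 1.64-fold with peaks up to 1 kb apart merged and 2.82-fold for neighbours within 5 kb (18.8% against 6.64%). Merging peaks up to 1 kb apart was not combined with placement within 1 Mb bins, so the excess left under both is unknown. Merging of touching peaks could change little, since it left 15382 of 15384 peaks. The density of X relative to the autosomes (0.238 to 0.294) and that of chromosome 11 relative to the others (1.44 to 1.54) stayed within their bootstrap intervals in all 6 alternatives each. The difference in score between grouped and single peaks did not keep its call. Within width deciles its size-weighted mean turned to 0.617. The difference fell short of the threshold with peaks of 200 bp or more (-0.32) and with peaks at or above the median score (-3.34, permutation p = 0.058). In the other 6 alternatives it remained negative and past the threshold. For the setting at the median score, which left 7712 peaks by construction, the cause was not tested. The unknown read depth limits all of these values, since regions below the authors' threshold are not in the list. No paired analysis was possible because each group has 1 library. The settings meant for promoters, gene lists and motifs were not run, for want of an annotation or sequence of mm9.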

Other observations

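The tests in this part were chosen after the result was seen, except the test of narrow peaks against random placement, whose prediction was written before its result.

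Narrow peaks were less depleted on X than wider ones, and no such difference was resolved on chromosomes 11 and 19. Peaks under 200 bp ranged over the autosomes from 1.05 per Mb on chromosome 3 to 1.75 on chromosome 11, with a coefficient of variation of 15.2%, and peaks of 200 bp or more from 3.42 per Mb on chromosome 14 to 7.15 on chromosome 11, with 21.5%, a difference in spread that was not tested. On X, the density relative to the autosomes was 0.452 for narrow peaks (95% bootstrap interval 0.330 to 0.583) and 0.238 for wider ones (0.184 to 0.291), and these intervals do not overlap. On chromosome 11 the ratios were 1.34 for narrow peaks (1.10 to 1.58) and 1.54 for wider ones (1.27 to 1.83), and on chromosome 19 they were 1.12 (0.864 to 1.39) and 1.39 (1.07 to 1.69), with overlapping intervals in both cases.

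The 3383 narrow peaks scored 61.3 units above the wider ones at the median (140.02 against 78.7). Narrow peaks were thus not the low-scoring end of the list. A first explanation, weak and thinly covered peaks that fall short of the usual width, was written down after these scores were seen. The scores are therefore no independent test of it, and the list holds no read counts by which coverage could be judged. A second explanation, read pile-ups scattered without regard to the other peaks, predicts no more narrow peaks near wider ones than random placement gives. Of the narrow peaks, 15.9% lay within 10 kb of a wider peak. This was above the highest of 1000 random placements (10.2%) and the highest of 1000 placements within the same 1 Mb bin (14.4%, mean 12.6%). Width limits of 180 and 250 bp gave 16.2% and 15.6%, also above the highest random placement over whole chromosomes (10.8% and 9.55%). Placement within 1 Mb bins was not run at these limits, and narrow peaks within 1000 bp of a wider one were not set apart. These shares argue against pile-ups scattered evenly over a chromosome or its 1 Mb bins as the whole account. Random positions could fall in unsequenced or repeated stretches where no peak can be called. Pile-ups kept to the remaining sequence are therefore not excluded. The random mean was 8.67% for narrow peaks, and for wider peaks near each other the share was 25.8% against a random mean of 10.02%, but the difference between these excesses was not tested, and a mixture of pile-ups and bound sites among the narrow peaks stays open.

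Of the 10 highest-scoring peaks, 8 lay within 1000 bp of another peak, against 9.87% of all peaks, and these 8 come from 3 places, so no test was made of them. The lower of the 2 mitochondrial scores stood at percentile 99.9 of the nuclear peaks. Of the 36 autosomal peaks that started below 3.1 Mb, beside the centromere, 25 were those of the densest window on chromosome 9, and the other 11, on 7 chromosomes, had a median score of 138. The list holds no copy numbers, and no explanation of the highest scores was tested.

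Of the 154 peaks at or above the 99th percentile of score, 10 lay in the densest window on chromosome 9 and 2 on the mitochondrial chromosome, and the other 142 lay elsewhere. Without the 10 densest windows and the mitochondrial chromosome, 15262 peaks remained, among them the 4 peaks with the score of 3100 on chromosomes 2 and 17, and the densest window held 9 peaks. The densest windows left were on chromosome 6 (115912294 to 116000310) and on chromosome 10 (77451576 to 77548118 and 79099752 to 79199584), with 9 peaks each and median scores of 72.3, 86.2 and 97.4. Random placement of the remaining peaks over their chromosomes gave a highest window count with a median of 7 that also reached 9.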
